A study of Mus musculus with 8 samples.

How the data were processed

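The libraries came from enteric neurons, the nerve cells of the gut wall, taken from the colons of mice aged 4 weeks. Per the labels' protocols, colon cells were dissociated with enzymes, stained with antibodies to CD24 and CD56 and sorted by flow cytometry into tubes of lysis buffer with about 250 cells each. Libraries were made with a Smart-seq kit, which copies and amplifies RNA from very small inputs. Per the labels, 4 WT and 4 Emb knockdown mice were used, and 4 libraries carry each genotype. The labels do not state that each tube held the cells of 1 mouse, so p-values measure the spread between these libraries, part of which may be technical. How the knockdown was made is not given in the sources used here.

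The authors deposited 1 table of whole-number counts per gene, not normalized, for 55414 mouse genes in 8 libraries. Per the submitters' processing notes, cutadapt (a tool that trims adapter sequence) and the genome build mm10 were used. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. Reads from overlapping genes, antisense partners and near-identical copies (ribosomal protein pseudogenes, histocompatibility genes) could be split in ways that the table does not show. Gene symbols were taken from the table. Coordinates and exon lengths were taken from GENCODE release M21, which is on GRCm38, the assembly that mm10 names; 52133 of the 55414 identifiers were found there.

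Total counts ranged from 698930 to 954191 in WT and from 2024372 to 2712754 in Emb knockdown. Amplified reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

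Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its defaults (minimum count 10, minimum total 15), libraries were scaled with TMM factors, and quasi-likelihood models with robust estimation and group as the only term were fitted to the deposited counts. P-values were adjusted by the Benjamini-Hochberg method over the 11353 genes tested, with a threshold of 0.05. Values per library are TMM-normalised CPM, and log2 CPM used a prior count of 2. Standard errors were derived from the log2 fold change and the F statistic. Single values were compared with exact two-sided permutation tests over the 70 assignments of 8 libraries, whose smallest possible p is 0.02857. For genes with 1 to 3 counts in a group, the ratio of summed counts, each divided by the summed TMM-scaled library sizes of its group, is given with an exact 95% Clopper-Pearson interval.

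A total of 47 gene lists were fixed before the data were examined; of their 1044 genes, 1040 matched a single identifier. Lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM with its preset correlation of 0.01. Beside it stand camera with a correlation estimated per list, and fry. The p of fry tests whether the members of a list move, on balance, one way, and its mixed p tests whether they change in either direction; neither compares a list with other genes. The lists for other cell types were also summed as CPM per library over all their members in the table.

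The named genes are Emb, Cd24a and Ncam1 (the genes of the sort antigens), and the 10 genes in each direction with the largest change among those past the adjusted p, with mean log2 CPM of at least 1, no overlap between the groups and a proper symbol. Where fewer than 10 qualified, the places went to the smallest unadjusted p under the same expression and symbol rules. Up to 4 members of each described list were named by smallest unadjusted p, and up to 3 of each list of other cells by highest mean CPM; some members chosen this way are not reported here. Lists that were not called are described by their median where the text gives one; that choice was made after seeing the data.

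Genes of olfactory, vomeronasal and trace amine receptors (1506 protein-coding genes), which colon neurons are not known to use broadly, were summed as a measure of background. A gene's counts per exonic kilobase were divided by those of the receptor genes in the same library. This measure was chosen after seeing the data. The background was not even across genes: the vomeronasal receptor gene Vmn1r13 lay at 208 to 318 times it in WT and 103 to 168 times in Emb knockdown.

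The fit was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries. Of genes changed 4-fold, 0% passed the adjusted p and 55.2% had an unadjusted p under 0.05; at 16-fold the shares were 7.2% and 83.6%. Of simulated copies of Emb lowered 4-fold, 0% passed the adjusted p. In each of these runs few of the 11353 genes were changed, 100 of them in the runs with copies of Emb. The adjusted p is harder to pass when few genes change. Camera called 5 of 5 raised lists and 0 of 200 unchanged lists. Those lists held random genes simulated independently of one another. They cannot show how often camera with its preset correlation makes false calls on correlated genes. In the real data the estimated correlation reached 0.216 in the immediate early and dissociation response list.

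The alternatives fixed in advance were DESeq2 size factors, upper quartile factors or library totals in place of TMM; no filter, or CPM above 5 in at least 4 libraries; limma voom with sample quality weights; the DESeq2 1.42.0 Wald test; a replicate block; 1 surrogate variable from sva 3.50.0; mitochondrially encoded genes left out; each library left out in turn; robust estimation off; and other thresholds. Despite its description as a stricter filter when planned, the CPM filter kept more genes, 13583. Added after seeing the data were thinning to an equal count outside ribosomal RNA, leaving out ribosomal RNA with Gm10800 and Gm10801, scaling to the receptor genes, and keeping Emb in fits whose filter removed it.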

Results

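The data were counts per gene from 8 libraries of sorted enteric neurons of mouse colon at 4 weeks of age, 4 from WT mice and 4 from Emb knockdown mice. Emb encodes embigin, a membrane glycoprotein of the immunoglobulin superfamily that partners with monocarboxylate transporters. By its title the study asked how lowering Emb affects the development of enteric neurons.

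The libraries of the 2 genotypes differed in depth and make-up. The total count was 808592 ± 115826 in WT and 2399162 ± 344119 in Emb knockdown (SD, n = 4 each; exact permutation p = 0.02857, the smallest possible; 0.0571 adjusted over 10 library measures). Rn18s-rs5, annotated as small-subunit ribosomal RNA, took 8.72% ± 4.00 of the counts in WT and 36.5% ± 5.53 in Emb knockdown (exact permutation p = 0.02857, adjusted 0.0571). Outside ribosomal RNA the libraries held 725928 ± 107997 and 1447447 ± 107757 counts. Genes of olfactory, vomeronasal and trace amine receptors together held 7846 ± 2262 counts in WT and 9726 ± 2309 in Emb knockdown (exact permutation p = 0.343), which was 0.959% and 0.420% of the counts. The predicted genes Gm10800 and Gm10801 took 11.0% ± 4.64 and 5.17% ± 2.39 (exact permutation p = 0.114). Spearman correlations of log2 CPM across genes were 0.351 to 0.390 between WT libraries, 0.428 to 0.487 between Emb knockdown libraries and 0.281 to 0.401 across genotypes. On the first principal component, with 24.8% of the variance, Emb knockdown replicate 1 lay farthest out at 127, against 11.7 to 42.3 for the other Emb knockdown libraries and -64.2 to -38.5 for WT.

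**Figure D1:**
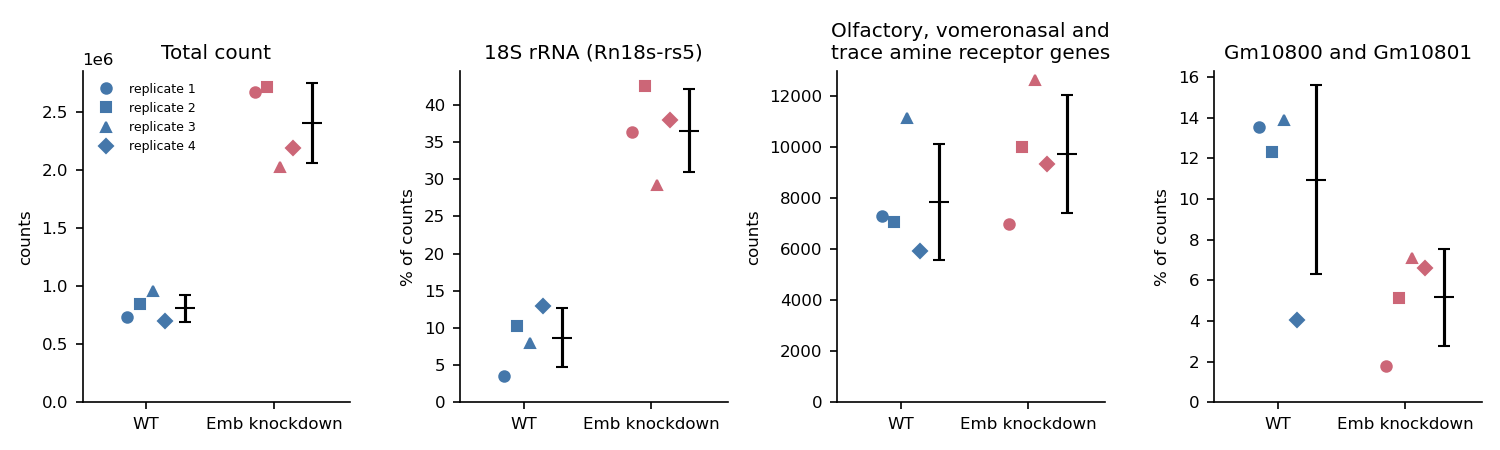
Total counts, percent of counts from Rn18s-rs5, counts of receptor genes and percent of counts from Gm10800 and Gm10801 in each library (points, shaped by replicate), with mean and SD beside them (n = 4 per genotype). Rn18s-rs5 took 29.2% to 42.5% of counts in the Emb knockdown libraries and 3.55% to 13.0% in WT.

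Emb itself was counted few times in every library. Emb (ENSMUSG00000021728, GRCm38 chromosome 13, 117208536 to 117274415, plus strand, protein coding) had 4, 6, 22 and 16 counts in WT replicates 1 to 4 and 5, 25, 3 and 5 in Emb knockdown replicates 1 to 4. In TMM-normalised CPM this was 12.8 ± 8.22 in WT and 5.33 ± 5.33 in Emb knockdown (SD, n = 4 each; exact permutation p = 0.171). The log2 fold change was -1.24 ± 0.82 (SE; 95% interval -3.03 to 0.55; edgeR adjusted p = 0.529), so no decrease was detected. Emb lay below every WT library in 3 of 4 Emb knockdown libraries, and Emb knockdown replicate 2, at 13.2 CPM, lay within the WT range. The estimate was -2.21 without Emb knockdown replicate 2 (edgeR adjusted p = 0.354), -0.77 without WT replicate 4 (adjusted p = 0.810), -2.04 with library totals alone (adjusted p = 0.239) and -0.60 when scaled to the receptor genes (adjusted p = 0.741).

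Of the genes of the sort antigens, only Ncam1 lay well above the receptor-gene background in every library. It lay at 11 to 86.7 times that background in WT and 56.2 to 256 times in Emb knockdown. Cd24a had 1, 13, 15 and 6 counts in WT replicates 1 to 4. It lay at 0.293 to 3.94 times the background in WT and 1.93 to 46 times in Emb knockdown, so its WT counts may be background. Cd24a, which encodes CD24, had 9.02 ± 5.80 CPM in WT and 31.5 ± 45.7 in Emb knockdown (log2 fold change 1.78 ± 1.02, edgeR adjusted p = 0.470). Emb knockdown replicate 1 held 99.9 CPM of Cd24a, and without it the log2 fold change of Cd24a was -0.09. Ncam1, which encodes CD56, had 459 ± 547 and 912 ± 643 CPM (log2 fold change 0.99 ± 0.87, edgeR adjusted p = 0.647). WT replicate 1 held 1278 CPM of Ncam1 against 140 to 221 in the other WT libraries; the log2 fold change of Ncam1 was 2.38 without it and 0.42 without Emb knockdown replicate 1.

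**Figure D2:**
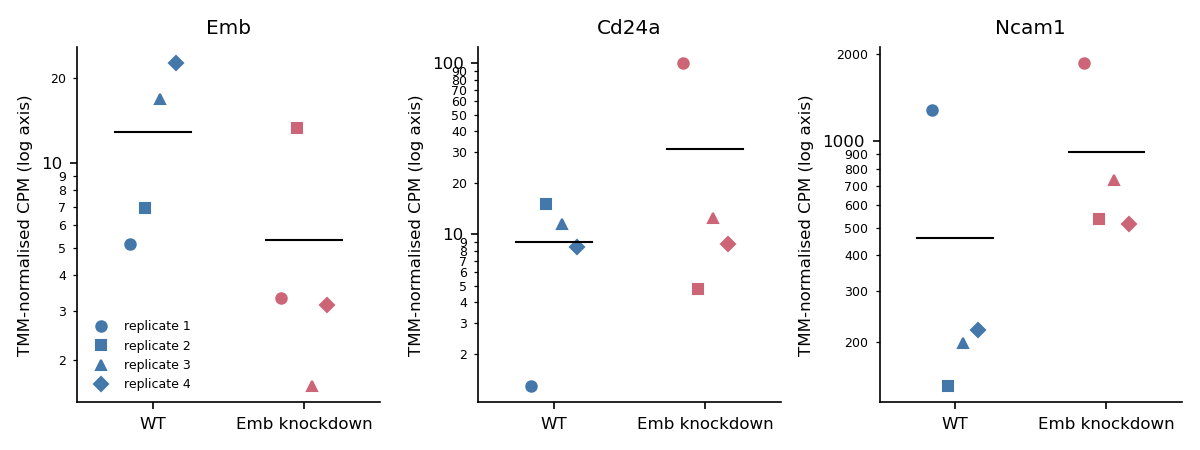
TMM-normalised CPM of Emb, Cd24a and Ncam1 in each library on a log axis (points, shaped by replicate), with lines at the means of 4 libraries per genotype. Emb knockdown replicate 2 lies within the WT range for Emb at 13.2 CPM, and Emb knockdown replicate 1 stands apart for Cd24a at 99.9 CPM.

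The genes with the lowest p in the direction of Emb knockdown were of several kinds, among them an immediate early gene, an Fc receptor, a lipase inhibitor and a lysosomal enzyme. Nr4a1, an orphan nuclear receptor induced as an immediate early gene, had 2.24 ± 2.16 CPM in WT and 727 ± 644 in Emb knockdown (SD, n = 4 each; log2 fold change 8.29 ± 1.30, edgeR adjusted p = 0.121). Fcgr3, a low-affinity receptor for immunoglobulin G, had 2.98 ± 3.40 and 209 ± 155 CPM (log2 fold change 6.08 ± 1.14, edgeR adjusted p = 0.185). G0s2, an inhibitor of triglyceride lipase, had 1 count over the WT libraries and 480 over Emb knockdown, a ratio of 258 after division by the TMM-scaled library sizes, with a counting interval of 46.1 to 10200 (edgeR adjusted p = 0.0719). Ngdn, a regulator of translation, had 3 and 827 counts, a ratio of 148 after the same division, with a counting interval of 50.5 to 720 (adjusted p = 0.0719). Gaa, the lysosomal acid glucosidase that degrades glycogen, had a log2 fold change of 3.88 ± 0.72, and Pdlim1, an actin-associated PDZ and LIM protein, 3.71 ± 0.64. Plac9 (5.26 ± 0.93), Olfml2b (4.20 ± 0.70), Ccdc34 (4.09 ± 0.72) and Rn18s-rs5 (2.71 ± 0.46) complete the 10 with the smallest p, and none passed the adjusted p.

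In the other direction stood genes of several kinds. Itgam, the alpha chain of a leukocyte integrin, had 3800 ± 1990 CPM in WT and 393 ± 232 in Emb knockdown (log2 fold change -3.27 ± 0.75, edgeR adjusted p = 0.275). Prkag3, a regulatory subunit of AMP-activated protein kinase, had 219 ± 209 and 9.09 ± 2.76 CPM (log2 fold change -4.58 ± 1.01), and Kif13a, a kinesin motor, 564 ± 829 and 14.1 ± 4.27 (-5.31 ± 1.22, and -3.35 without WT replicate 4, which held 1800 CPM). Hp, the haemoglobin-binding plasma protein haptoglobin, had 65.5 ± 47.6 and 7.21 ± 1.89 CPM (-3.17 ± 0.70), and Kremen2, a receptor for Dickkopf inhibitors of Wnt signalling, 17.7 ± 8.31 and 1.27 ± 0.86 (-3.68 ± 0.83). Trcg1, Sowahc, Zfp275, Nckap5l and Wdcp had log2 fold changes of -2.97, -3.99, -2.84, -3.08 and -2.49; Sowahc was at -2.61 without WT replicate 2. The edgeR adjusted p of these 10 genes lay at 0.275 to 0.292, and none passed.

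By edgeR, 0 of 11353 genes passed an adjusted p of 0.05, with a lowest adjusted p of 0.0719; 1508 genes had an unadjusted p under 0.05 (981 higher and 527 lower in Emb knockdown), where 567.6 are expected by chance. The DESeq2 Wald test called 749 genes on the same counts (526 higher, 223 lower), limma voom called 0, and edgeR without a filter on low counts called 910 (725 higher, 185 lower). The groups did not overlap in 940 genes (8.28% against 2.86% by chance), 458 of them higher and 482 lower. The scaling set the balance of directions: with library totals alone, 375 of 2079 genes with an unadjusted p under 0.05 were higher in Emb knockdown, and the median log2 fold change of all genes was -0.67 against 0.04 with TMM; when scaled to the receptor genes, 2060 of 2201 were higher and the median was 0.64.

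Of the 42 gene lists tested, 5 rose in Emb knockdown by camera and none fell. The immediate early and dissociation response list rose most (median log2 fold change 2.15, camera adjusted p = 3.67e-09), with all 18 tested members higher. The ribosomal protein list rose (median 1.69, adjusted p = 4.66e-07), with 30 of the 35 tested members higher, out of 79 fixed. The interferon response list rose (median 1.55, adjusted p = 5.24e-05), with 21 of 24 higher. The macrophage and dendritic list (median 1.43, adjusted p = 0.00279) and the list of cytokines and inflammation (median 0.90, adjusted p = 0.0223) rose as well. None of these 5 calls held with an estimated correlation (adjusted p = 0.305 with an estimated correlation for each), and fry gave each an adjusted p of 0.0553 for movement one way and at most 0.00222 for change in either direction. The latter does not single out these lists, since 9 lists that were not called also had a fry adjusted p under 0.05 for change in either direction, with fibroblast markers lowest at 3.50e-04. The mean log2 CPM of each of the 5 lists was higher in 4 of 4 Emb knockdown libraries than in every WT library (exact permutation p = 0.02857, 0.109 adjusted over 42 lists). The libraries with more of these transcripts were also those with the larger share of Rn18s-rs5, 36.5% against 8.72%. With library totals alone the medians of the 5 lists ranged from 0.19 to 1.43, against a median of -0.67 for all genes.

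**Figure D3:**
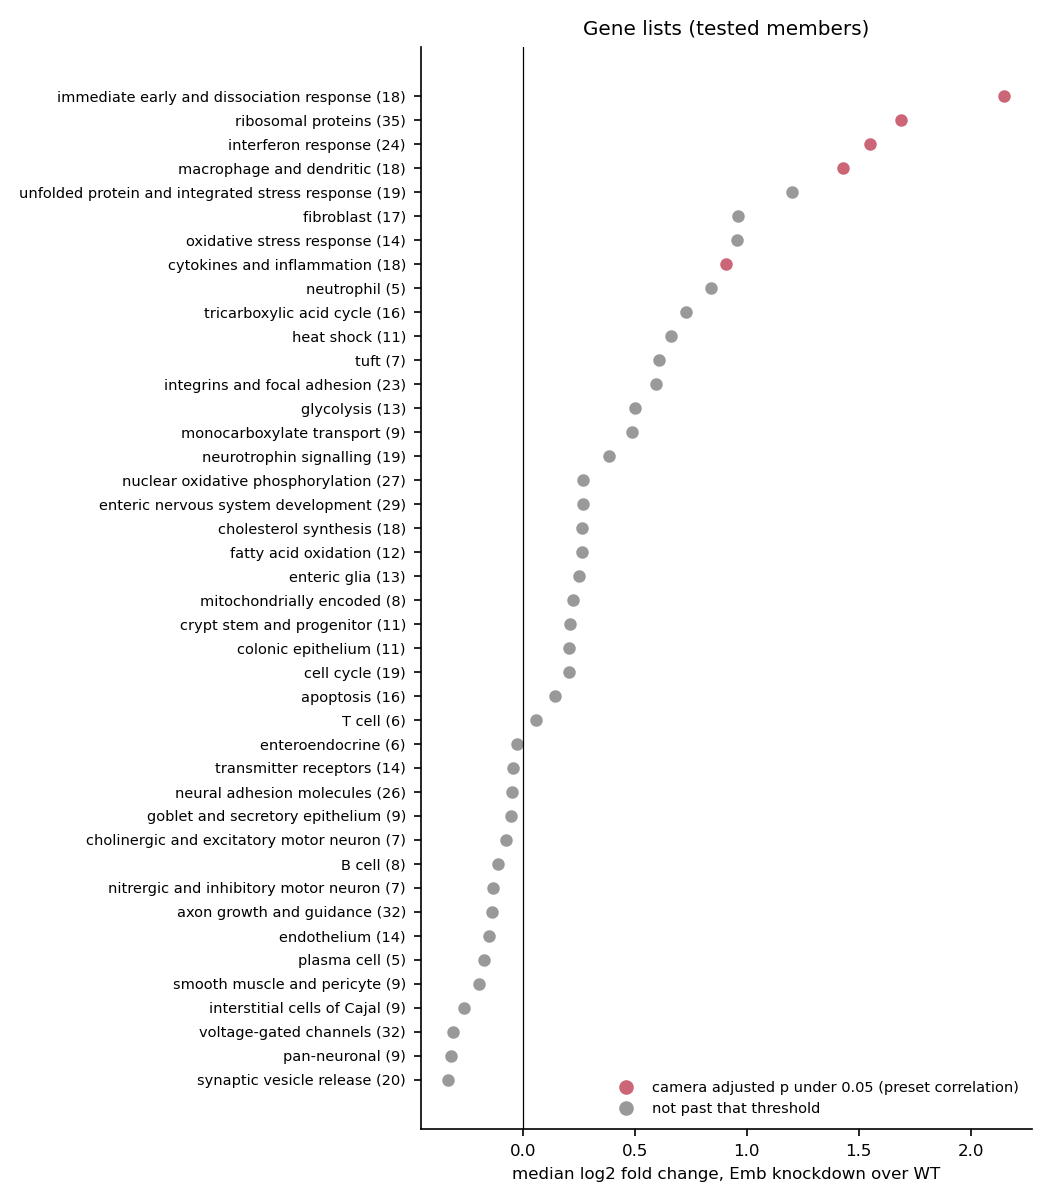
Median log2 fold change (Emb knockdown over WT) of the tested members of each of the 42 gene lists, with the number of tested members in parentheses and lists past the camera threshold in red. Medians run from -0.33 for synaptic vesicle release to 2.15 for the immediate early and dissociation response; with library totals alone the medians of enteric glia, glycolysis, heat shock, fibroblast, monocarboxylate transport and nuclear oxidative phosphorylation were below 0.

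Within the immediate early list, which holds transcription factors and feedback regulators induced within minutes of stimulation or tissue dissociation, 0 members passed over all genes and 10 of 18 passed when adjusted over the list alone. Beside Nr4a1, the smallest p belonged to Jun (179 ± 70.9 CPM in WT, 1520 ± 1550 in Emb knockdown; log2 fold change 3.08 ± 0.83), Fos (60.9 ± 29.8 and 537 ± 478; 3.14 ± 0.87), both subunits of the AP-1 factor, and Dusp1, a phosphatase of MAP kinases (140 ± 92.8 and 1080 ± 755; 2.95 ± 0.81). Ribosomal proteins had 0 members past the threshold over all genes and 9 of 35 adjusted over the list alone. Rplp1 had 183 ± 143 CPM in WT and 1970 ± 1330 in Emb knockdown (log2 fold change 3.43 ± 0.82), and Rpl26 and Rpl35a had log2 fold changes of 6.13 ± 1.26 and 4.51 ± 1.10. The median of the ribosomal protein list was 2.60 without Emb knockdown replicate 2 and 2.94 without Emb knockdown replicate 4. Reads of these genes can be shared with their many pseudogenes. Only 35 of the 79 ribosomal protein genes had enough counts to be tested. Rpl26 had 4, 7, 1 and 8 counts in WT and passed the filter through Emb knockdown, and members kept that way tend to be higher. Over all 79, the median member lay at 1.40 ± 0.33 times the receptor-gene background in WT and 4.53 ± 1.77 times in Emb knockdown. The median protein-coding gene lay at 1.01 ± 0.2 and 1.71 ± 0.16 times.

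The interferon list had 0 members past the threshold over all genes and 6 of 24 adjusted over the list alone. Among its members were B2m, the light chain of class I histocompatibility molecules (918 ± 438 CPM in WT and 5410 ± 3460 in Emb knockdown; log2 fold change 2.56 ± 0.67), the class I heavy chain H2-D1 (3.38 ± 1.05, and 1.65 without Emb knockdown replicate 1) and the immunoproteasome subunit Psmb9 (2.32 ± 0.73). In the list of cytokines and inflammation 0 members passed over all genes and 6 of 18 adjusted over the list alone, 5 of them higher. Vcam1, an adhesion molecule for leukocytes, had a log2 fold change of 3.11 ± 0.78, the NF-kappaB regulators Nfkbia and Nfkbiz 4.44 ± 1.16 (2.94 without Emb knockdown replicate 1) and 3.71 ± 1.12, and the chemokine Cxcl1 1.73 ± 0.54. In this list 15 members were higher and 3 lower. Chosen after its value was seen, Tnfaip3, another NF-kappaB regulator, was lower at -1.80 ± 0.64 and passed over the list alone. The camera call of this list was lost without WT replicate 2 (median 0.76, adjusted p = 0.224), WT replicate 3 (0.85, 0.0740) or Emb knockdown replicate 3 (0.99, 0.0585). It was also lost with 1 surrogate variable (1.18, 0.0705) and after thinning to an equal count outside ribosomal RNA (0.65, 0.0715), while the median stayed above 0.

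**Figure D4:**
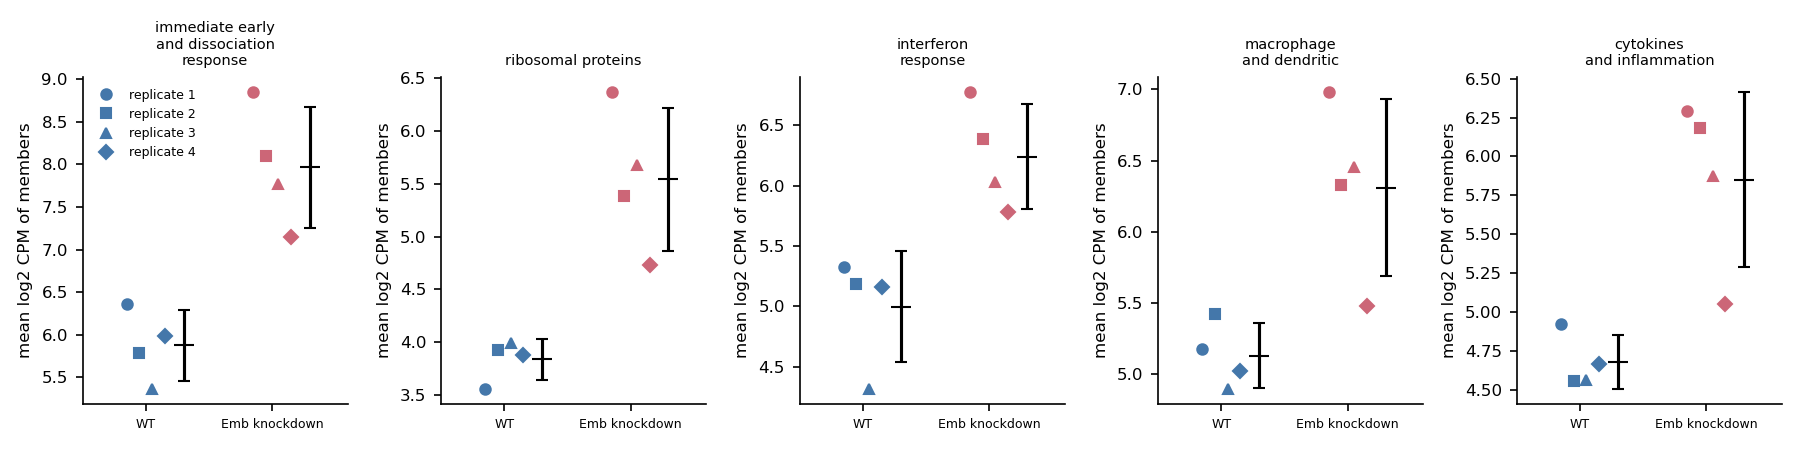
Mean log2 CPM of the tested members of the 5 lists past the camera threshold in each library (points, shaped by replicate), with mean and SD (n = 4 per genotype). All 4 Emb knockdown libraries lie above all 4 WT libraries in each list; none of the calls held with an estimated correlation (adjusted p = 0.305).

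Stress and metabolic lists had higher medians without passing the threshold. The unfolded protein and integrated stress response list had a median log2 fold change of 1.20 (camera adjusted p = 0.0590), led by the amino acid transporter Slc7a5 (2.66 ± 0.74), the transcription factor Atf4 (2.33 ± 0.78), Ppp1r15a (2.72 ± 0.96) and Dnajc3 (1.52 ± 0.62). The oxidative stress list had a median of 0.96 (adjusted p = 0.0590), with the metallothionein Mt1 at 365 ± 180 CPM in WT and 1400 ± 440 in Emb knockdown. The heat shock list had a median of 0.66 (adjusted p = 0.0807), with the chaperone Hsp90aa1 at 3.10 ± 0.92; its median was -0.20 with library totals alone, and ran from 0.17 without Emb knockdown replicate 1 to 2.19 without WT replicate 3. Tricarboxylic acid cycle genes had a median of 0.73 (adjusted p = 0.108), glycolysis genes 0.50 (0.696) and nuclear oxidative phosphorylation genes 0.27 (0.902), and the last pair lay at -0.20 and -0.22 with library totals alone. Leaving out single libraries moved these medians, and the farthest values follow. Oxidative stress lay at 0.57 without WT replicate 1 and the tricarboxylic acid cycle at 0.35 without Emb knockdown replicate 1. Glycolysis lay at 0.20 without Emb knockdown replicate 4, and oxidative phosphorylation ran from 0.10 without Emb knockdown replicate 3 to 1.15 without Emb knockdown replicate 2 and 1.40 without WT replicate 2. Members past the threshold adjusted over the list alone numbered 0 in each of these 6 lists. Camera did call the stress response list without WT replicate 2 (adjusted p = 0.0465), WT replicate 4 (0.0333), or Emb knockdown replicate 2 (0.0348), 3 (0.0257) or 4 (0.00246), and the heat shock list without WT replicate 3 (0.0228) or Emb knockdown replicate 3 (0.0338). Camera also called the stress response list with limma voom (0.0292), after thinning to an equal count outside ribosomal RNA (0.00577) and with no filter (0.00544). It called the heat shock list with library totals alone (0.0456), where the median of all genes was -0.67, and with no filter (0.0376). With no filter it further called oxidative stress (0.0122), the tricarboxylic acid cycle (0.00585) and oxidative phosphorylation (0.0344).

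No list of neuronal genes passed the threshold. Synaptic vesicle release genes had the lowest median, -0.33, with 15 of 20 members lower (camera adjusted p = 0.355): Rph3a, an effector of vesicle exocytosis, had 29.9 ± 13.8 CPM in WT and 5.67 ± 3.44 in Emb knockdown (log2 fold change -2.38 ± 0.69), the plasma membrane SNARE Stx1a -2.97 ± 1.26 (-0.19 without WT replicate 1), Syt11 2.14 ± 0.79 (1.15 without Emb knockdown replicate 1) and Napb 2.16 ± 0.92. Pan-neuronal genes had a median of -0.32 and a mean of 0.24 over 9 tested members (adjusted p = 0.941), with Map1b, a microtubule-associated protein, at 2.52 ± 0.78, the ubiquitin hydrolase Uchl1 at 3.32 ± 1.40 (2.00 without Emb knockdown replicate 1), and the RNA-binding proteins Celf4 and Elavl3 at -1.40 ± 0.68 (-0.87 for Celf4 without WT replicate 1) and -0.97 ± 0.61. Voltage-gated channels had a median of -0.31 (adjusted p = 0.696), with Kcnq3, Cacna1h and Kcnd2 at -2.22 ± 0.88, -2.35 ± 0.93 and -1.38 ± 0.55 and Kcnb2 at 1.85 ± 0.73. Cacna1h was at -0.57 without WT replicate 3, and Kcnq3 at -1.16 without WT replicate 2. Left-out libraries moved the pan-neuronal median from -0.66 (without Emb knockdown replicate 3) to -0.07 (without Emb knockdown replicate 4), synaptic vesicle release to -0.63 (without Emb knockdown replicate 4) and voltage-gated channels to 0.18 (without WT replicate 4). When scaled to the receptor genes the 3 medians were 0.23, 0.21 and 0.29. The monocarboxylate transport list, which holds the transporters that embigin partners with, had a median of 0.49 (adjusted p = 0.941), with Slc16a1 at 3.78 ± 1.42 (0.38 without Emb knockdown replicate 1), Slc16a7 at 1.15 ± 0.54, Slc16a13 at -1.62 ± 1.27 (-0.32 without WT replicate 2) and Slc5a8 at 0.94 ± 0.75; the median was -0.23 with library totals alone and -0.30 without Emb knockdown replicate 3. In these 4 lists 0 members passed when adjusted over the list alone.

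Among markers of other cell types, the macrophage and dendritic list passed by camera with 14 of 18 members higher and 4 lower (adjusted p = 0.305 with an estimated correlation). It had 0 members past the threshold over all genes and 6 of 18 adjusted over the list alone, 5 of them higher. C1qa, a complement subunit made by macrophages, had 1490 ± 763 CPM in WT and 3940 ± 999 in Emb knockdown (log2 fold change 1.41 ± 0.61). Its other abundant members were lower: Itgam is given above, and the fractalkine receptor Cx3cr1 had 1150 ± 315 and 277 ± 300 CPM (-2.06 ± 1.04). Chosen after their values were seen, the mannose receptor Mrc1 (3.19 ± 0.76), the invariant chain Cd74 (2.79 ± 0.79) and the class II chain H2-Aa (2.13 ± 0.84) were higher. Summed over the list, CPM was 6920 ± 2685 in WT and 6688 ± 1588 in Emb knockdown (exact permutation p = 0.914), a sum that in WT came mostly from Itgam and Cx3cr1. The median member lay at 3.56 ± 0.94 times the receptor-gene background in WT and 22.5 ± 8.48 times in Emb knockdown (exact permutation p = 0.02857). For the median protein-coding gene the values were 1.01 ± 0.2 and 1.71 ± 0.16 times.

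Enteric glia markers had a median of 0.25 (camera adjusted p = 0.696; -0.44 with library totals alone, 0.67 without WT replicate 1 and 0.13 without WT replicate 2). Among them Gfap, an intermediate filament gene of glia, had 82.4 ± 30.0 CPM in WT and 147 ± 77.4 in Emb knockdown (log2 fold change 0.83 ± 0.65, edgeR adjusted p = 0.603; 0.41 without Emb knockdown replicate 1). Fibroblast markers had a median of 0.96 (adjusted p = 0.696; -0.02 with library totals alone, 0.27 without Emb knockdown replicate 3 and 0.29 without Emb knockdown replicate 1), with the collagen genes Col5a1 and Col1a1 at 2.26 ± 0.82 and 1.36 ± 0.83 and the actin-severing protein Gsn at 1.52 ± 0.97. Col1a1 was at 0.62 without Emb knockdown replicate 1, and Gsn at 0.99 without Emb knockdown replicate 2. Summed over the lists, CPM was 726 ± 158 in WT and 1362 ± 430 in Emb knockdown for fibroblasts and 1606 ± 668 and 767 ± 540 for endothelium (exact permutation p = 0.0571 for each). The design could hardly let a single summed list pass after adjustment over all of them.

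The other 25 lists tested did not pass by camera. The adjusted p was 0.696 for integrins and focal adhesion, 0.712 for tuft cells, 0.878 for enteric nervous system development, 0.902 for neurotrophin signalling and for crypt stem and progenitor cells, and 0.958 for enteroendocrine cells. It was 0.941 for cholinergic and excitatory motor neurons, nitrergic and inhibitory motor neurons, transmitter receptors, axon growth and guidance, neural adhesion molecules, apoptosis, cell cycle, cholesterol synthesis, fatty acid oxidation, mitochondrially encoded genes, smooth muscle and pericytes, interstitial cells of Cajal, endothelium, colonic epithelium, goblet and secretory epithelium, neutrophils, T cells, B cells and plasma cells. Their medians lay between -0.26 and 0.84, and median, mean and camera direction differed in sign in 13 of the 42 lists. The lists for sensory neurons and interneurons, natural killer and innate lymphoid cells, mast cells and basophils, erythroid cells and platelets, and mesothelium had under 5 tested members and were not tested.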

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

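The tests of depth, background, macrophages, glia, Emb counts and the spread of single libraries were chosen after the results were seen; the test of Emb without Emb knockdown replicate 2 and the other splits of the libraries were set before their results were seen.

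The 8 libraries can be split 4 against 4 in 35 ways. Genes with an unadjusted p under 0.05 numbered 1508 in the real split. Only 1 of 35 splits, the real one, gave as many, with 1130 the highest of the others. However, 1 of 35 is the smallest share possible, and several counts were compared over the same splits. No adjustment for those comparisons was made, so chance was not excluded. The real split also ranked first for the 749 genes of DESeq2 (1 of 35 splits, highest other 283) and the 910 genes of edgeR without a filter (1 of 35, highest other 692). Both settings also called genes in splits that mix the genotypes. These counts come from the same 8 libraries and are not separate evidence. For the adjusted edgeR count, 35 of 35 splits gave as many as the real 0, with a highest other of 0. For the 4 lists outside other cell types, 4 of 35 splits gave as many, with 6 the highest of the others, and for the 1 list of other cell types 4 of 35 gave as many, with a highest other of 1, so chance was not excluded for the lists.

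The 5 lists that were higher in Emb knockdown sat in libraries with more counts. After thinning every library to the same count outside ribosomal RNA, the median log2 fold change of the 113 members was 1.53 (range of 20 draws 1.41 to 1.65) against 1.55 at full depth. The genes were those kept at full depth, and random removal of counts leaves a scaled fold change about unchanged on average. The thinning therefore cannot decide whether differences that go with depth lay behind the pattern. Genes that every cell uses and whose lists were not called (oxidative phosphorylation, tricarboxylic acid cycle and glycolysis, 112 genes) lay at 1.54 ± 0.28 times the receptor-gene background in WT and 3.44 ± 1.20 times in Emb knockdown, a ratio of 2.23 (exact permutation p = 0.02857), so a smaller share of RNA-derived counts over a constant background in WT may account for part of the pattern. More macrophages in the sort cannot be told apart from other causes. The summed CPM ratio of their list was 0.966 (exact permutation p = 0.914), but the WT sum came mostly from Itgam and Cx3cr1. The median member of that list rose 6.32-fold over the background. On the same measure the median protein-coding gene also rose, from 1.01 ± 0.2 times in WT to 1.71 ± 0.16 times in Emb knockdown (exact permutation p = 0.02857). An effect of the knockdown, or a stronger dissociation response in those cells, stays open and was not tested apart from the library differences.

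Emb did not pass the threshold although the libraries are labelled as its knockdown. Of simulated copies of Emb lowered 4-fold 0% passed the adjusted p, but so did 0% of genes in general. At 16-fold 31% of the copies passed against 7.2% of genes. These adjusted shares are not comparable. All copies in a run had the same fold, while the genes mixed several folds, which moves the cutoff of the adjusted p. At an unadjusted p under 0.05 the copies passed less often (39% against 55.2% at 4-fold, 64% against 83.6% at 16-fold). Too few counts cannot be told apart from the spread between libraries. Without Emb knockdown replicate 2 the log2 fold change was -2.21 (edgeR adjusted p = 0.354, over a range of -2.21 to -0.77 with each library left out). That library had 25 Emb counts against 3 to 5 in the rest of its group, so a lower estimate without it was bound to follow. Only the size of the shift is informative, and Emb did not pass there either. Emb also lay at 1.22 ± 0.80 times the receptor-gene background in WT and 0.799 ± 0.82 times in Emb knockdown, so its counts may be background in both genotypes. The counts therefore cannot serve as a check of the labels, in either direction.

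Pan-neuronal genes lay close to the background in libraries labelled as neurons, at 1.51 ± 0.14 times in WT and 2.09 ± 0.19 times in Emb knockdown. Genes that every cell uses were as near to it in WT, at 1.54 times, so a low number of RNA-derived counts could account for weak neuronal markers there. In Emb knockdown those genes lay farther above the background than pan-neuronal genes, at 2.39 to 5.16 times against 1.86 to 2.28 times. That reading therefore rests on the WT libraries alone. The enteric glia list lay above the pan-neuronal list in 8 of 8 libraries, which would also be seen with glia among the sorted cells. Of its members, 18.8% to 37.5% in WT and 43.8% to 62.5% in Emb knockdown lay over 5 times the background. Among protein-coding genes the shares were 8.71% to 11.8% and 12.8% to 22.4%. The abundance of different genes is not comparable, so glia among the sorted cells cannot be told apart from other causes. The sort on CD24 and CD56 is not stated to remove glia. No biological explanation was tested for this pattern.

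Single libraries stood far from the other 3 of their genotype in 15 of 226 groups of 4 values examined, where chance flags about 1 in 20, or 11.3. The share of Gm10800 and Gm10801 was 4.07% in WT replicate 4 against 12.3% to 13.9% in the other WT libraries. In log2 CPM, WT replicate 4 stood apart for G0s2 (1.55), WT replicate 2 for Olfml2b (2.61), Hsp90aa1 (5.46) and Atp5a1 (4.80), WT replicate 1 for Vcam1 (5.73) and Prdx1 (4.08), and WT replicate 3 for Cxcl1 (4.13) and for the mean of the interferon list (4.31). Among Emb knockdown libraries, replicate 1 stood apart for Kremen2 (0.61), Syt11 (8.99) and Mdh2 (9.17), and replicate 3 for Pfkm (3.18), Ndufa11 (2.41) and Prdx1 (6.20). Some of these gaps were a few counts. G0s2 had 1 count in WT replicate 4 and 0 in the rest of WT, and Olfml2b 4 in WT replicate 2 against 1 to 2. Kremen2 had 0 counts in Emb knockdown replicate 1 against 3 in each other library of that genotype.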

How the results depend on the processing

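The settings with thinning, with ribosomal RNA, Gm10800 and Gm10801 left out, with scaling to the receptor genes and with Emb kept in the fit were chosen after seeing the data. The count of 0 genes by edgeR at an adjusted p of 0.05 became 749 with the DESeq2 Wald test, 910 with no filter, 2 with library totals only and 3 at an adjusted p under 0.1; it stayed at 0 under the other settings, each left-out library included. The 4 called lists outside other cell types became 9 with no filter, and 0 with an estimated correlation or fry; the 1 list of other cell types became 0 with an estimated correlation or fry. Without one library at a time these counts were 4 to 5 and 1. The cause of these changes was not tested. Emb stayed negative and not past the threshold throughout, from -2.21 to -0.60; without any 1 Emb knockdown library, after thinning and without ribosomal RNA it fell below the filter, and its values there come from fits that kept it.

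The replicate block left 0 genes, 4 and 1 called lists and an Emb log2 fold change of -1.46 (edgeR adjusted p = 0.721), and changed no call. Libraries with the same number did not deviate together (correlations 0.0113 to 0.0337), so the numbers were not treated as pairs; 2 of 4 WT libraries matched their own number best.

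Signs turned only in results that had not passed. With library totals only, medians were -0.44 for enteric glia, -0.0229 for fibroblasts, -0.20 for glycolysis, -0.20 for heat shock (which camera called there, adjusted p = 0.0456), -0.23 for monocarboxylate transport and -0.22 for oxidative phosphorylation; that scaling moved the median of all genes to -0.67. With scaling to the receptor genes, which moved it to 0.64, the medians were 0.21 for pan-neuronal genes, 0.23 for synaptic vesicle release and 0.29 for voltage-gated channels. The pan-neuronal median was 0.0447 with no filter, 0.00613 with limma voom, 0.0297 with the block and 0.11 with 1 surrogate variable. Monocarboxylate transport was -0.22 with voom, -0.34 with the block and -0.30 to 0.42 with libraries left out. With libraries left out, Cd24a ran from -0.0905 to 2.21, Dnaja1 from -0.11 to 1.84 and voltage-gated channels from -0.38 to 0.18. Among the 25 lists given by adjusted p alone, the median changed sign in 118 of 530 values and 0 passed the threshold. Lists described by their median and not called passed in 15 values, 8 of them for the stress response list and 4 for the heat shock list. The 5 called lists kept their direction in all 110 values and missed the threshold in 15. Of 1650 values for 81 named genes, 85 passed the threshold, 51 with DESeq2, 33 with no filter and 1 with library totals.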

Other observations

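Some of the most abundant genes had counts that hardly followed the depth of the library; they were chosen after their values were seen. Gm15266 had 13547 to 21499 counts in the WT libraries and 13055 to 14835 in Emb knockdown, and the protocadherin gene Pcdhga12 had 7407 to 12899 and 7518 to 8597, while total counts differed 2.97-fold. Other abundant genes followed or exceeded the depth: Junb, an AP-1 subunit, had 121 to 2405 counts in WT and 6283 to 21395 in Emb knockdown, and the class I gene H2-K1 836 to 2158 and 3401 to 17422.

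Protein-coding genes outside the receptor families lay over 5 times the receptor-gene background in 10.4% ± 1.57 of cases in WT and 18% ± 4.02 in Emb knockdown (SD, n = 4 each; exact permutation p = 0.02857, chosen after seeing the data). Elavl4 and Tubb3, which mark neurons, lay at 0.291 to 1.94 and 0 to 2.13 times that background in WT.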
